A study of Homo sapiens with 14 samples.

How the data were processed

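Total RNA was sequenced from K562 cells, an established line from a human chronic myeloid leukaemia, that carry dCas9-KRAB, a catalytically inactive Cas9 fused to a repressor domain and used for CRISPR interference. Per the labels, ribosomal RNA was depleted and strand-specific libraries were made with the NEBNext Ultra II Directional kit. The labels list 14 libraries: 2 of untransduced cells, 3 with a guide against AAVS1 (the negative control), 2 with guides against TASOR, 3 with guides against TASOR2, 2 with guides against MPP8 and 2 with guides against PPHLN1 (Periphilin). RNA of the transduced cells was taken 7 days after transduction.

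Per the submitters' processing notes, cutadapt and Bowtie2 were used and the genome build was hg38. Their versions, the read counter, the annotation release, the handling of duplicate reads, whether reads were counted over exons or whole genes, and whether strand was used in counting are not given in the sources used here. The authors deposited 1 table of 35805 gene rows with 6 value columns. Per the file headers and the values, the untransduced column holds the mean log2 value of that group, in a unit close to reads scaled to a common depth. The other 5 deposited columns were found from the values to be each group's mean log2 value divided by the untransduced mean log2 value, so they are quotients of 2 log2 values and not fold changes. Each quotient was multiplied by the untransduced value, which gave back the group mean log2 value. In 102 rows the untransduced value lies within 0.05 of 0, and rounding can make the recovered value less exact there. No column of values was left unused.

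Whether the recovered scale was right was checked on low values. In each column a single commonest lowest value marked genes with no reads, and the steps above it matched means of log2 whole reads, with 0 reads set to 0.9 reads. All low values tested (100% in each of the 6 columns, within a relative tolerance of 0.001) were whole-read means. The steps corresponded to means of 3 libraries for sgAAVS1 and of 2 libraries for each other group. For TASOR2 this is 2 libraries where the labels list 3, and which of the 3 guides entered the mean is not given in the sources used here. The value of 1 read gave the geometric mean depth per library: 7406967 reads for untransduced cells, 6202797 for sgAAVS1, 6945068 for TASOR, 5857938 for TASOR2, 5925919 for MPP8 and 5963709 for PPHLN1. A group with 0 reads allows up to 3 counts over the group, a log2 value of -2.63 for sgAAVS1, -2.21 for TASOR, -1.97 for TASOR2, -1.98 for MPP8, -1.99 for PPHLN1 and -2.30 for untransduced cells.

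A per-library test with limma and the gene set tests planned before the data were examined need single libraries. The table holds only group means, so no test, p-value, SD or n over libraries is given, and guide-to-guide and replicate-to-replicate spread could not be measured. A rule of size took the place of the test. A gene was called higher or lower when the log2 means differed by at least 1, the higher mean was above 0 on the log2 scale, and the 95% counting interval of the difference excluded 0. The counting interval takes Poisson error at the recovered depth, and covers counting error only. Genes entered when at least 1 of the 6 means was above 0, and rows sharing a symbol were reduced to the row with the highest mean (87 rows dropped), which left 16433 tested genes. The rule was tried on simulated data with counting error alone, so its rates leave out spread between libraries or guides. Genes to be changed were drawn from those with an sgAAVS1 mean above 1, so recovery at lower means was not measured. In data simulated for the TASOR comparison, the rule recovered 97.9% of 95 genes changed by 1.5 on the log2 scale and 100% of 105 genes changed by 2. For an unchanged group simulated for the MPP8 comparison, 0.564% of 15947 genes were called, and the interval held the true difference in 95.1% of 15574 genes.

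The deposited scaling left the median difference from sgAAVS1 over all tested genes at 0.16 for TASOR, 0.07 for TASOR2, 0.12 for MPP8, 0.17 for PPHLN1 and 0.05 for untransduced cells, in log2 units. List medians are therefore given relative to the median of all tested genes. Gene lists (19 in number) were fixed before the data were examined, and cover interferon-stimulated genes, antigen presentation, innate sensing, inflammation, HUSH partners, numbered zinc finger genes, clustered protocadherins, germline, histone, erythroid, megakaryocyte and myeloid, proliferation, stress, heat shock, non-blood, lymphoid, mitochondrially encoded, small structured RNA and ribosomal protein genes. A list's median was placed among 10000 random lists of the same size matched on mean value in 20 bins. The percentile describes these means and is not a test.

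The rule for named genes, also fixed beforehand, took the 4 targeted genes, up to 15 higher and 10 lower genes per knockdown by size of difference, up to 3 members of each list per direction, TAF7, MORC2 and SETDB1, and up to 8 genes per direction in the other comparisons. Its condition on single libraries could not be used. In its place the genes of the first 15 and 10 had to pass the rule of size against untransduced cells also. Genes named only by a clone or locus identifier were counted and not named. Gene names are those of the table, with the current symbol where it differs.

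Of the tested genes, 15965 (97.2%) were matched to GENCODE release 29 on the same build by name and place, 2742 of them by identical place alone. That annotation gave gene type, exon number, and the length and GC content of the longest transcript. Overlaps between knockdowns were set beside the product expected of independent lists and beside 200 simulations of unchanged groups that share the sgAAVS1 mean. These simulations drew their spread from untransduced minus sgAAVS1 differences, which may hold real effects too. The results were also computed with no filter, a filter 2 log2 units higher, median centring, quantile normalization, a pseudocount of 1, and other controls. A lower limit of 1.5-fold on the difference, no counting interval, the rule applied against both controls and removal of the trend on transcript GC in 30 bins were added after seeing the data. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.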

Results

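The study asked how the transcriptome of K562 cells changes on loss of subunits of HUSH and HUSH2, complexes that silence transposons and other genes through chromatin. TASOR marks HUSH, TASOR2 marks HUSH2, and MPP8 and Periphilin (gene PPHLN1) are known to act with both. Total RNA was measured in 6 groups: untransduced cells, cells with the control guide sgAAVS1, and knockdowns of TASOR, TASOR2, MPP8 and PPHLN1. All values are the authors' group means on a log2 scale, with no SD or n, because single libraries were not analysed here. The geometric mean depth per library ranged from 5857938 reads in TASOR2 to 7406967 in untransduced cells. A value after ± is the half-width of the 95% counting interval of a log2 difference and covers counting error only. A gene is called higher or lower when it differs by at least 1 on the log2 scale, with a higher mean above 0 and a counting interval without 0.

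Each targeted gene was lowest in its own knockdown. TASOR (FAM208A in the table, chromosome 3, 56620133 to 56683237 on hg38, protein-coding) had a mean of 7.22 in sgAAVS1 and 3.29 in the TASOR knockdown, a log2 difference of -3.93 ± 0.25. TASOR2 (FAM208B, chromosome 10, 5684838 to 5763740) went from 7.45 to 6.03 in its knockdown, -1.42 ± 0.11. MPHOSPH8, which encodes MPP8 (chromosome 13, 19633681 to 19673459), went from 6.52 to 4.70, -1.83 ± 0.18. PPHLN1 (chromosome 12, 42238447 to 42459715) went from 6.57 to 5.27, -1.29 ± 0.15. Transcript left in the knockdown was 6.56% of the sgAAVS1 mean for TASOR, 37.5% for TASOR2, 28.2% for MPHOSPH8 and 40.8% for PPHLN1, so knockdown depth differed between the groups. No other knockdown brought a targeted gene past the rule, but FAM208B stood at 8.18 in the PPHLN1 knockdown, 0.73 ± 0.07 above sgAAVS1, and FAM208A at 7.69 in the TASOR2 knockdown, 0.47 ± 0.08 above it. Median centring or quantile normalization moved the PPHLN1 difference to -1.51 or -1.48, beyond its counting interval, and the TASOR2 difference was -1.66 against untransduced cells.

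**Figure D1:**
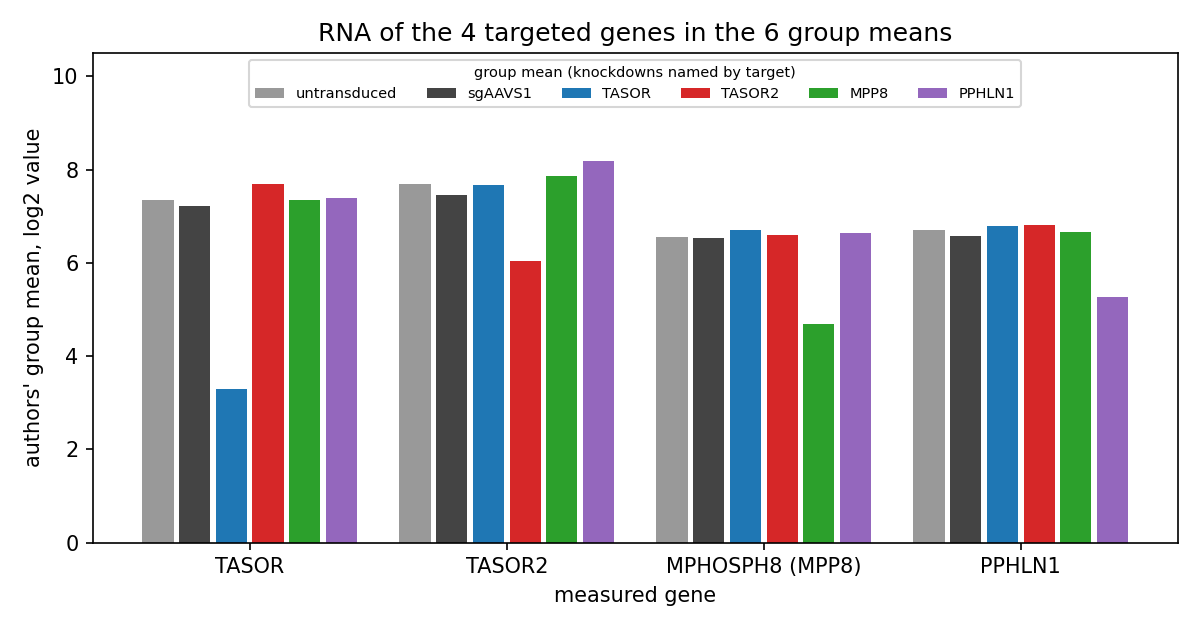
Authors' group mean log2 value (y axis) of the 4 targeted genes (x axis) in the 6 groups, 1 bar per group mean. Each gene is lowest in its own knockdown, from 3.29 for TASOR to 6.03 for TASOR2.

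Untransduced cells differed from sgAAVS1 cells without any knockdown, which sets the background for every comparison with sgAAVS1. THBD, which encodes the anticoagulant receptor thrombomodulin, had a mean of -2.73 in sgAAVS1 and between 3.13 and 3.46 in the other 5 groups, and was 5.97 ± 0.72 higher in untransduced cells. ZNF660, a zinc finger gene, was 3.47 ± 1.04 higher in untransduced cells and was also higher than sgAAVS1 in all 4 knockdowns. NGEF, a guanine nucleotide exchange factor, and CXADR, the coxsackievirus and adenovirus receptor, were 2.98 ± 0.99 and 2.87 ± 1.02 higher in untransduced cells. CXCL8, a neutrophil chemokine, was 1.90 lower in untransduced cells (-1.90 ± 0.37), and BMP10, a growth factor, differed by -2.74 ± 1.22. In all, 215 genes were higher and 36 lower in untransduced cells, and 12 genes were lower in sgAAVS1 than in all 5 other means. Quantile normalization turned the counts to 105 higher and 89 lower, and a filter 2 log2 units higher left 19 and 8.

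In the TASOR knockdown, protocadherins of the gamma cluster were higher. All 22 clustered protocadherins tested were gamma genes (chromosome 5, from 141330571), which encode neuronal adhesion proteins. Of these, 21 were higher than sgAAVS1 and none lower, with a list median of 1.64 relative to all genes. PCDHGA5 was 2.04 ± 0.34 higher, and PCDHGA1 2.07 ± 0.70. IL6, an inflammatory cytokine, was 1.98 ± 0.50 higher, and the collagen gene COL28A1 2.39 ± 0.52. TDRD5 and TDRD6, germline Tudor-domain genes, were 2.48 ± 0.61 and 1.59 ± 0.48 higher, but 1.35 and 0.85 above untransduced cells, where TDRD6 did not pass the rule. BDKRB1, a bradykinin receptor, was 3.07 ± 1.07 higher, and DSG1, a desmosomal cadherin, 2.64 ± 1.01. Against sgAAVS1 lower genes were few, with SMPD3, a neutral sphingomyelinase, going from 4.25 to 2.75 and AQP9, an aquaporin, at -1.78 ± 1.38.

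Of the 71 interferon-stimulated genes tested, 1 was higher in the TASOR knockdown and none lower, and the list median was 0.04, at the 79.5th percentile of random lists matched on mean value. With no filter on low values it was 0.29, because the median of all genes, which is subtracted, went from 0.16 to -0.09. Without the filter that median falls among genes with few or no reads and follows the lowest values of the columns. The gene called higher was TNFSF10, which was 1.77 ± 0.95 higher but was also higher in untransduced cells. SAMD9 fell short of the rule, with a mean of 4.14 in TASOR, 3.24 in sgAAVS1 and 3.08 in untransduced cells. IFIT1 (-0.64 in TASOR, -2.02 in sgAAVS1) and MX1 (-0.89 and -1.97) had TASOR means too low for the rule. IFIH1 had means of 2.84, 2.64 and 3.16 in TASOR, sgAAVS1 and untransduced cells. In TASOR 45 of the 71 genes lay above the median of all genes. Of 461 numbered zinc finger genes 15 were higher and none lower, and 3 of them passed against both controls. The protocadherin list stood at the 100th percentile, but untransduced cells also had 8 of the 22 higher, with a median of 0.52. Against both controls 12 of the 22 were higher in TASOR, and against untransduced cells alone the median was 0.92. In all, 305 genes were higher and 51 lower, of which 83 and 19 also passed the rule against untransduced cells. Unchanged groups simulated against the same sgAAVS1 mean had medians of 103 higher and 59 lower. The 51 lower genes are fewer than 59, but the count depends on scaling and was 105 after median centring. Whether lower genes exceed the background is therefore not decided. Protocadherin gamma gene models overlap and share their last exons, so reads may be split or shared between them and single members are uncertain. The 22 members are therefore not independent. In every knockdown, the count of members called and the percentile among random lists of separate genes can overstate the change at this locus. The balance of calls depended on scaling, with 166 higher and 105 lower after median centring and 131 and 132 after quantile normalization. Against untransduced cells alone the counts were 193 and 128, and a filter 2 log2 units higher left 75 and 9.

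In the TASOR2 knockdown, some interferon-stimulated genes were higher and no protocadherin was. SAMD9, an interferon-induced antiviral factor (chromosome 7, 93099513 to 93118023), had a mean of 3.24 in sgAAVS1 and 6.15 in the knockdown, 2.91 ± 0.24 higher. IFIH1, which encodes the double-stranded RNA sensor MDA5, was 2.75 ± 0.30 higher, SP110, a nuclear body gene, 2.34 ± 0.27, HERC6, an interferon-induced ubiquitin ligase, 2.91 ± 1.05, and IFIT1, which binds viral RNA, 2.71 ± 1.11. Of the 71 interferon-stimulated genes 20 were higher and none lower, with a list median of 0.44 at the 100th percentile of matched random lists; 13 passed against both controls. Of 18 antigen presentation genes 3 were higher: the immunoproteasome subunits PSMB8 (2.30 ± 0.48) and PSMB9 (1.91 ± 0.51) and the peptide transporter TAP1 (1.27 ± 0.18). None of the 22 protocadherins was higher or lower (list median 0.08, at the 92.5th percentile). Among random lists matched on GC content also, the percentile was 98.56, and with the trend on transcript GC removed the median was 0.16. Against untransduced cells, with no GC trend removed, the protocadherin median was -0.54.

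Some zinc finger genes were also higher in the TASOR2 knockdown: 39 of 461 were higher, 1 lower and 421 did not pass, with a median of 0.24. Against both controls 17 were higher, and against untransduced cells alone the median was 0.11. ZNF829 was 2.58 ± 1.11 higher; ZNF568 was 2.28 ± 1.11 higher, but 0.99 above untransduced cells, where it did not pass. Against sgAAVS1 lower genes were nearly as many as higher ones. They included COL6A1, a collagen VI chain, at -2.81 ± 1.27, FITM2, a lipid droplet gene, at -2.41 ± 0.57, PCK1, the gluconeogenic phosphoenolpyruvate carboxykinase, at -2.40 ± 1.08, and CHAC1, a glutathione-degrading enzyme of the stress list, at -1.46 ± 0.20. In all, 350 genes were higher and 326 lower, of which 159 and 212 also passed against untransduced cells. The TASOR2 mean stood apart from the other knockdowns, but not from untransduced cells, in the direction of its trend with GC content. Over genes with a mean log2 value above 5, its difference from sgAAVS1 went with transcript GC content (Spearman's rho -0.70 across genes, which are not independent), against 0.18 for TASOR, 0.31 for MPP8, 0.34 for PPHLN1 and -0.54 for untransduced cells. Among 15965 genes with a GC value, 327 were higher and 314 lower; with the GC trend removed 294 and 258 were, of which 268 and 227 had been called before, and the zinc finger median became 0.13. Median centring gave 294 higher and 432 lower and quantile normalization 373 and 260. Against untransduced cells alone 211 were higher and 519 lower.

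In the MPP8 knockdown, most protocadherins and some interferon-stimulated and zinc finger genes were higher. SAMD9 was 2.65 ± 0.24 higher, IFIH1 2.40 ± 0.30, the antiviral GTPase gene MX1 2.30 ± 1.19, and GIMAP2, an immune-associated GTPase gene, 2.34 ± 0.48. Of the 71 interferon-stimulated genes 17 were higher and none lower (median 0.42, 100th percentile), 15 of them against both controls, and of 18 antigen presentation genes 6 were higher, among them PSMB8 (2.23 ± 0.49), PSMB9 (2.12 ± 0.50) and TAPBPL (1.42 ± 0.58). Of 22 protocadherins 19 were higher, with PCDHGA5 at 1.98 ± 0.35 and PCDHGA6 at 1.87 ± 0.31 and a list median of 1.36, and IL6 was 2.01 ± 0.51 higher. Among zinc finger genes 47 of 461 were higher, none lower and 414 did not pass; 27 were higher against both controls. Their median was 0.11, beside 0.08 in untransduced cells, and 0.049 with untransduced cells as the control. ZNF233 was 2.46 ± 1.16 higher. ZNF606 was 2.58 ± 0.98 higher, but 1.22 above untransduced cells; it is 1 of the 12 genes lower in sgAAVS1 than in all 5 other means. ZIK1, a zinc finger gene outside the numbered list (chromosome 19, 57578456 to 57593777), was 3.25 ± 0.53 higher.

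Lower genes were few in the MPP8 knockdown against sgAAVS1. There were 44, beside a median of 59 in simulated unchanged groups. The count depends on scaling and was 89 after median centring, so whether lower genes exceed the background is not decided. Apart from MPHOSPH8, most of the lower genes had low means, such as BCL2L15 at -1.78 ± 1.35 and IGLON5 at -1.44 ± 1.32. In all, 258 genes were higher and 44 lower, of which 109 and 18 also passed against untransduced cells. Median centring gave 189 and 89, and quantile normalization 186 and 81. A filter 2 log2 units higher left 100 higher and 4 lower. Against untransduced cells alone 191 were higher and 154 lower. Against both controls 9 of 22 protocadherins were higher, and against untransduced cells alone their median was 0.42.

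In the PPHLN1 knockdown, the protocadherins and some interferon-stimulated and zinc finger genes were higher. Of the 71 interferon-stimulated genes 23 were higher and none lower (median 0.42, 100th percentile), with MX1 at 2.98 ± 1.08, SAMD9 at 2.86 ± 0.24 and IFIH1 at 2.76 ± 0.29. Of 18 antigen presentation genes 6 were higher, led by PSMB9 (2.47 ± 0.48). All 22 protocadherins were higher (a 2.82-fold median), with PCDHGB2 at 2.21 ± 0.30; 10 of them passed against both controls, and against untransduced cells alone the log2 median was 0.67. IL6 was 2.34 ± 0.49 higher. Of the 461 zinc finger genes 61 were higher and none lower, 45 of them against both controls, with ZNF256 at 3.03 ± 1.04, and ZIK1 was 3.67 ± 0.52 higher. NPAP1, an imprinted gene on chromosome 15, was 2.87 ± 0.36 higher. TNS4, a tensin, had no reads in sgAAVS1 and was 3.20 ± 1.02 higher. Its PPHLN1 mean was 8.26-fold above the limit of 3 counts over the sgAAVS1 group, leaving out the counting error of the PPHLN1 mean. The erythroid genes CA1, a carbonic anhydrase, and SLC4A1, the band 3 anion exchanger, were 1.21 ± 0.26 and 1.17 ± 0.16 higher, but 0.38 and 0.82 above untransduced cells, where neither passed. Of the 43 erythroid genes 34 lay above the median of all genes (list median 0.13, 100th percentile).

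A set of genes was lower in the PPHLN1 knockdown than in both controls and in the MPP8 knockdown. DRAM1, a lysosomal membrane gene linked to autophagy (chromosome 12, 101877351 to 102012130), had a mean of 4.80 in sgAAVS1 and 2.36 in the knockdown, -2.45 ± 0.39, and its MPP8 mean was 2.59 ± 0.40 above its PPHLN1 mean. C15orf57 (current symbol CCDC32) was at -2.10 ± 0.21, TMEM92, a membrane protein gene, at -2.38 ± 0.77, FAM161A, a ciliary gene, at -2.55 ± 1.03, and MGST1, a microsomal glutathione transferase, at -1.78 ± 0.40. This condition was chosen after the values were seen and held for 23 genes. In 8 of them, DRAM1, C15orf57, MGST1 and PPHLN1 among them, all other means were above 3. The rule called 453 genes higher and 98 lower, of which 194 and 48 also passed against untransduced cells. Median centring gave 296 and 171, quantile normalization 275 and 182, untransduced cells as the control 249 and 125, and a filter 2 log2 units higher 175 and 26.

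**Figure D2:**
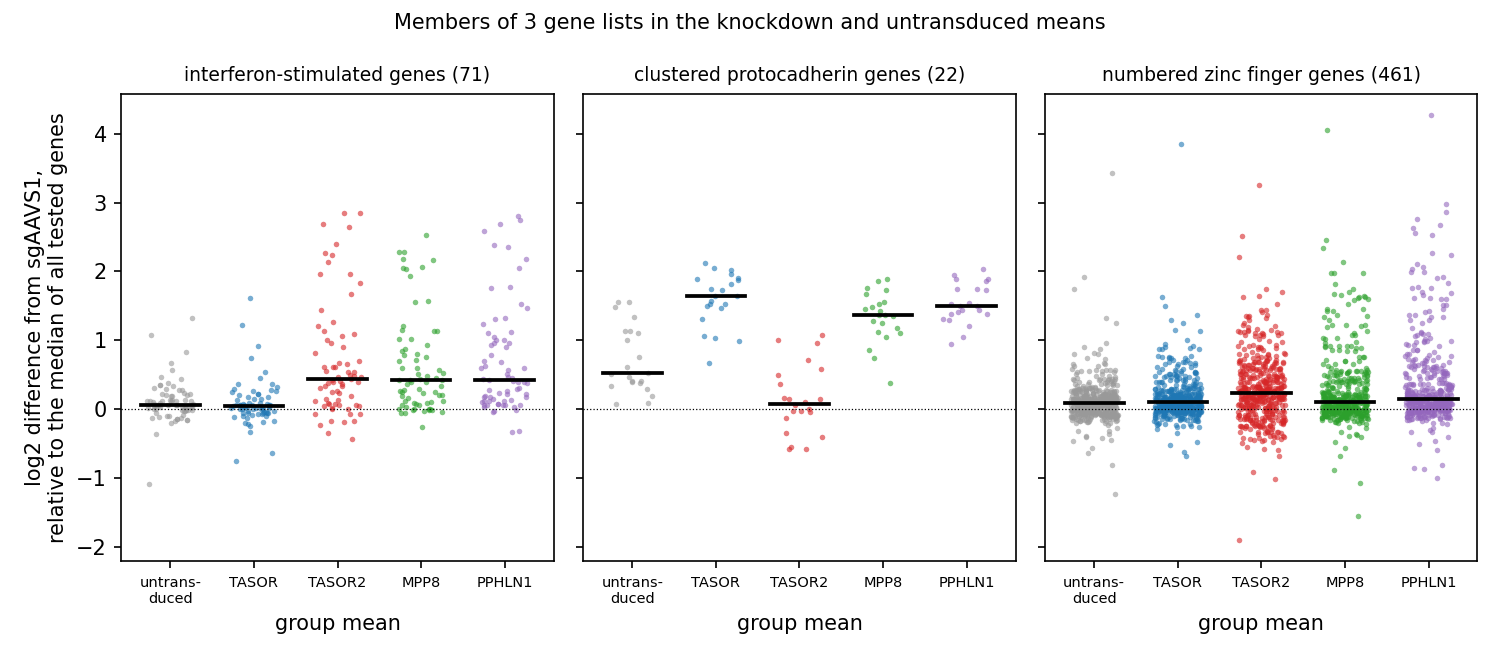
Log2 difference from sgAAVS1 relative to the median of all tested genes (y axis) for each member of 3 lists (1 point per gene, horizontal bar the list median) in the untransduced and knockdown means (x axis). Interferon medians are 0.04 in TASOR and 0.44, 0.42 and 0.42 in TASOR2, MPP8 and PPHLN1, and protocadherin medians are 1.64 in TASOR, 1.36 in MPP8 and 0.08 in TASOR2 (0.92, 0.42 and -0.54 against untransduced cells).

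On chromosome 19, where most primate KRAB zinc finger genes lie in clusters, 55 of 231 numbered zinc finger genes were higher in the PPHLN1 knockdown, 42 in MPP8, 31 in TASOR2, 8 in TASOR and 4 in untransduced cells. On the other chromosomes the counts were 6, 5, 8, 7 and 2 of 230. Against sgAAVS1, 26 zinc finger genes were higher in TASOR2, MPP8 and PPHLN1 alike, 5 in all 4 knockdowns, and 25 in MPP8 or PPHLN1 and neither TASOR nor TASOR2. Against both controls, 8 were higher in TASOR2, MPP8 and PPHLN1 alike and 0 in all 4. The 5 include ZNF660 and ZNF606, which were lower in sgAAVS1 than in all 5 other means. Zinc finger genes are a large family with similar sequences, and reads may be shared between members. Their list median lay at the 100th percentile in every knockdown and also in untransduced cells, where it was 0.08.

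Compared directly, without any control, the TASOR and TASOR2 knockdowns parted on the protocadherin and interferon lists. Of 22 protocadherins 19 were higher in TASOR than in TASOR2 and none lower, and of 71 interferon-stimulated genes none was higher and 14 were lower. The list medians of TASOR minus TASOR2 were 1.46 and -0.33. Part of the 1.46 may follow GC content: random lists matched to the protocadherins on mean value and GC had medians of 0.12 in TASOR and -0.23 in TASOR2 against sgAAVS1. With the GC trend removed, the protocadherin medians against sgAAVS1 were 1.64 in TASOR and 0.16 in TASOR2. HERC6 differed by -2.71 ± 1.17 and ZNF829 by -2.89 ± 1.31. FITM2 was higher in TASOR, by 2.82 ± 0.57. In all, 840 genes were higher and 215 lower in TASOR than in TASOR2. Among the 15965 genes with a GC value, 804 were higher and 198 lower; with the GC trend removed 666 and 182 were, of which 602 and 162 had been called before. Quantile normalization gave 352 higher and 432 lower over all genes.

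**Figure D3:**
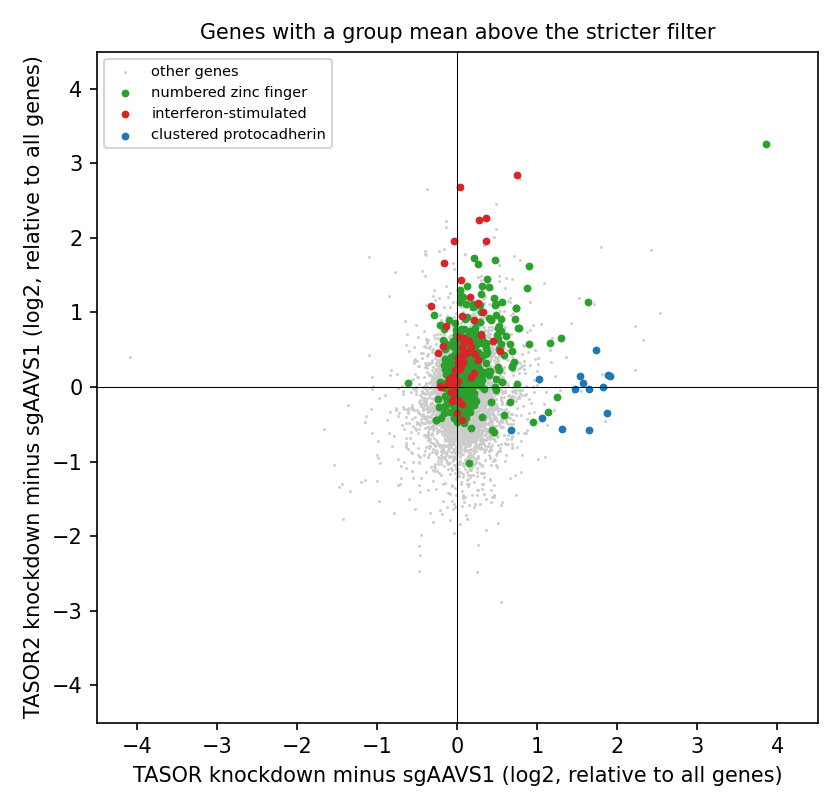
Log2 difference from sgAAVS1 in the TASOR knockdown (x axis) and the TASOR2 knockdown (y axis), both relative to the median of all tested genes, for 13699 genes with a group mean above 2 (1 gene lies outside the axes). Protocadherins (blue, 14 genes) lie to the right. Interferon-stimulated genes are red (62 genes); of all 71 tested, 60 were above the median of all genes in TASOR2 and 20 passed the rule. The zinc finger gene at the upper right is ZNF660, which was also higher in untransduced cells.

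MPP8 and PPHLN1 knockdowns were then set against TASOR and TASOR2. PSMB8 was 2.20 ± 0.54 higher in MPP8 than in TASOR. XAF1, an apoptosis-associated gene, had no reads in TASOR. Its PPHLN1 mean was 6.86-fold above the limit of 3 counts over the TASOR group, leaving out the counting error of the PPHLN1 mean. MPP8 minus TASOR gave 125 genes higher and 165 lower, and PPHLN1 minus TASOR gave 218 and 155. FAM71F2 (current symbol GARIN1A) and OSCP1 had their highest means in TASOR2, and differed by -3.67 ± 1.15 and -3.08 ± 1.29 in MPP8 minus TASOR2. COL6A1 was 3.56 ± 1.26 higher in MPP8 and 3.70 ± 1.26 higher in PPHLN1 than in TASOR2. MPP8 minus TASOR2 gave 617 genes higher and 242 lower, and PPHLN1 minus TASOR2 gave 800 and 239. The MPP8 and PPHLN1 means were nearest to each other, with 91 genes higher and 136 lower in MPP8, among the former DRAM1 and TMEM92. These comparisons have no replicate check, and the 4 knockdowns differ in how much target transcript was left.

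Genes called higher were shared between knockdowns. MPP8 and PPHLN1 shared 189 higher genes, TASOR and PPHLN1 128, TASOR2 and PPHLN1 117, TASOR and MPP8 93, TASOR2 and MPP8 84, and TASOR and TASOR2 44. Independent lists of the same sizes would share 7.11, 8.41, 9.65, 4.79, 5.50 and 6.50 genes, and unchanged groups against the same sgAAVS1 mean shared a median of 18 in simulation. The simulated groups had a median of 103 genes higher, fewer than the 258 to 453 of the knockdowns, so 18 is not a like-for-like value; as a share of the list, the 44 of 305 for TASOR and TASOR2 do not exceed 18 of 103. With the later-named knockdown of each pair set against untransduced cells, the same pairs shared 124, 63, 63, 38, 49 and 9, and with the first-named 94, 51, 43, 40, 40 and 19; for TASOR and TASOR2, independent lists would share 3.92 and 4.11. Part of the excess may come from the shared control, since 3 control libraries cannot be split. The covariance of log2 differences across genes was 0.088, 0.072, 0.053, 0.054, 0.037 and 0.033 for the pairs in the same order, beside a simulated 0.039 from the shared control. TASOR2 thus had covariances with TASOR and MPP8 below the simulated one. With the later-named or the first-named of a pair set against untransduced cells, covariances were -0.015 either way for TASOR and TASOR2, -0.011 or 0.0019 for TASOR2 and MPP8, and 0.0054 or -0.0076 for TASOR2 and PPHLN1. They were 0.052 or 0.027 for MPP8 and PPHLN1, 0.024 or 0.011 for TASOR and PPHLN1, and 0.0063 or 0.019 for TASOR and MPP8. Shared lower genes numbered between 12 and 22 per pair, where independent lists would share 0.137 to 1.94. The simulation gave a median of 13 and an upper 95% limit of 20, which only TASOR and TASOR2, with 22, exceeded. Simulated lists held a median of 59 lower genes, more than the 51 in TASOR and 44 in MPP8 and fewer than the 98 in PPHLN1 and 326 in TASOR2, so 13 is not a like-for-like value either.

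The other lists held few calls. HUSH partners had none in any knockdown among 23 genes. MORC2 and SETDB1, effectors of HUSH, differed from sgAAVS1 by 0.15 ± 0.08 and 0.20 ± 0.07 in TASOR and by 0.14 ± 0.09 and -0.03 ± 0.08 in TASOR2, and TAF7, a transcription factor subunit gene beside the protocadherins, by 0.15 ± 0.09 in TASOR and 0.28 ± 0.09 in PPHLN1. Germline genes numbered 2, 1, 2 and 6 higher of 50 in TASOR, TASOR2, MPP8 and PPHLN1, and 3 in untransduced cells. Innate sensing genes had 1 of 20 higher in TASOR2, MPP8 and PPHLN1 each, which was IFIH1, also in the interferon list. In the inflammation list of 18, IL6 was higher in TASOR, MPP8 and PPHLN1 and CXCL8 lower in TASOR, as in untransduced cells. Small structured RNAs had 1, 3, 1 and 3 of 20 higher, and 3 in untransduced cells. Erythroid genes had 2 of 43 higher in PPHLN1. The megakaryocyte and myeloid list of 18 had TUBB1 higher in TASOR and PPHLN1 and GP6 lower in TASOR2. The histone list of 56 had HIST1H2BA (current symbol H2BC1) higher in TASOR2, and the stress list of 24 had CHAC1 lower in TASOR2. The lymphoid list of 6 had CD79A higher in PPHLN1 (1.70 ± 1.22). The proliferation (37), heat shock (14), non-blood (7), mitochondrially encoded (13) and ribosomal protein (82) lists had no call in any knockdown. The mitochondrially encoded list, held as a measure of RNA quality, had medians of -0.05, 0.13, 0.08 and 0.04 in TASOR, TASOR2, MPP8 and PPHLN1, at the 51.5th, 93.9th, 100th and 99.3rd percentiles. Medians of the small structured RNAs, also a measure of RNA quality, were -0.21 in TASOR (0th percentile), 0.08 in TASOR2, 0.04 in MPP8 and 0.06 in PPHLN1, and -0.23 in TASOR minus TASOR2 (0.39th percentile). Ribosomal protein genes had medians of -0.12 in TASOR and -0.09 in untransduced cells, both at the 0th percentile, and between -0.01 and 0.02 in the other knockdowns. TASOR thus stood below the other knockdowns in these lists, as in the interferon list.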

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

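The lower limit of 1.5-fold, the rule without a counting interval, the rule against each control and the removal of the GC trend were chosen only after the results were seen; the other settings were chosen before. The deposited columns are group means, so the planned limma fits (with and without robust moderation, or of only the compared groups), the count-based test, camera, fry and the leave-one-out fits were not run. No paired analysis was possible because the deposited columns are group means. Depth limits genes with few reads: their counting intervals are wide, and spread between guides or replicates is not part of any interval. Of 328 values computed again, 64 could not move by construction, such as list medians under median centring or targets under a filter. Of the other 264, 147 stayed within their limits (1.5 times for counts, the counting interval for targets, a bootstrap interval for list medians), 116 moved and 1 reversed. The targeted genes were lower in their own knockdown in all 36 values computed for them; they were not computed again with the GC trend removed. The cause of the moves was not tested, except where the genes counted changed by construction.

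With no filter on low values, TASOR had 494 genes higher and 125 lower, MPP8 had 109 lower, PPHLN1 182 lower, untransduced cells 348 higher and 106 lower, and TASOR minus TASOR2 346 lower. List medians became 0.29 (interferon), 1.89 (protocadherin) and 0.36 (zinc finger) in TASOR, and the zinc finger median 0.16 in MPP8 and 0.26 in PPHLN1. The antigen presentation median in TASOR reversed from -0.09 to 0.16. Its own median stayed at 0.07, and the median of all genes, which is subtracted, went from 0.16 to -0.09 with the genes at low values. The reversal thus comes from the value subtracted and not from the antigen presentation genes. With a filter 2 log2 units higher, counts of higher and lower genes were 75 and 9 in TASOR, 135 and 110 in TASOR2, 100 and 4 in MPP8, 175 and 26 in PPHLN1, 19 and 8 in untransduced cells, and 405 and 71 in TASOR minus TASOR2. With a pseudocount of 1 they were 69 and 7, 129 and 71, 101 and 3, 186 and 23, 15 and 5, and 334 and 70, in the same order, and protocadherin medians were 1.03 in TASOR, 0.76 in MPP8 and 0.89 in PPHLN1.

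Median centring gave 166 higher and 105 lower in TASOR, 89 lower in MPP8, 296 higher and 171 lower in PPHLN1, and -1.51 for PPHLN1 in its knockdown. Quantile normalization gave 131 higher and 132 lower in TASOR, 81 lower in MPP8, 275 higher and 182 lower in PPHLN1, 105 higher and 89 lower in untransduced cells, and 352 higher and 432 lower in TASOR minus TASOR2. It also gave -0.0011 for the interferon median in TASOR and -1.48 for PPHLN1 in its knockdown. The share of higher genes went from 85.7% to 61.3% and 49.8% in TASOR, from 85.4% to 68.0% and 69.7% in MPP8, from 82.2% to 63.4% and 60.2% in PPHLN1 and from 51.8% to 40.5% and 58.9% in TASOR2 under the 2 scalings.

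With sgAAVS1 and untransduced cells together as control, the interferon median was -0.00087 in TASOR, protocadherin medians were 1.43, -0.13, 1.12 and 1.22 and zinc finger medians 0.068, 0.19, 0.067 and 0.11 in TASOR, TASOR2, MPP8 and PPHLN1. With untransduced cells alone, TASOR had 193 higher and 128 lower, TASOR2 211 higher and 519 lower, MPP8 154 lower and PPHLN1 249 higher. Interferon medians were then -0.0066 in TASOR and 0.31 in TASOR2, protocadherin medians 0.92, -0.54, 0.42 and 0.67 and zinc finger medians 0.024, 0.11, 0.049 and 0.083 in the 4 knockdowns, and TASOR2 in its knockdown was -1.66. Genes higher in a pair, with the first and then the second knockdown against untransduced cells, numbered 19 and 9 for TASOR and TASOR2, 40 and 38 for TASOR and MPP8, 51 and 63 for TASOR and PPHLN1, 40 and 49 for TASOR2 and MPP8, 43 and 63 for TASOR2 and PPHLN1, and 94 and 124 for MPP8 and PPHLN1.

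With a lower limit of 1.5-fold, higher and lower genes numbered 828 and 93 in TASOR, 823 and 779 in TASOR2, 534 and 83 in MPP8, 998 and 164 in PPHLN1, 491 and 88 in untransduced cells and 2006 and 415 in TASOR minus TASOR2. Without a counting interval MPP8 had 76 lower. With the rule applied against each control the counts were 83 and 19 in TASOR, 159 and 212 in TASOR2, 109 and 18 in MPP8, and 194 and 48 in PPHLN1. With the GC trend removed the zinc finger median in TASOR2 was 0.13.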

Other observations

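The tests of counting error, a shared effect, scaling and duplicate removal were chosen only after the results were seen, as were the gene sets of the next 2 paragraphs and the spread ratios to TASOR and untransduced cells; the tests of GC content, transcript length, zinc finger genes and intronless genes were written before. For the intronless test, the random lists were limited to named genes after a first run had been seen.

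Against both controls, 30 genes were higher in TASOR2, MPP8 and PPHLN1 alike, among them 11 interferon-stimulated genes (SAMD9, SAMD9L, IFIH1, MX1, USP18 and IFIT2 included), the antigen presentation genes PSMB8, PSMB9 and TAP1, and 8 numbered zinc finger genes such as ZNF528 and ZNF677. In TASOR, MPP8 and PPHLN1 alike, 22 genes were higher: 9 gamma protocadherins, IL6, COL28A1, RNF113B and C10orf25 (current symbol ZNF22-AS1) among them. Only ZIK1 and ZNF528-AS1 were in both sets and so higher in all 4 knockdowns.

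Of the 12 genes lower in sgAAVS1 than in all 5 other means, SNCG, a synuclein, and MMRN2, an endothelial extracellular matrix gene, overlap on chromosome 10, and RAB11FIP5, a vesicle transport gene, had means of 5.06 in sgAAVS1 and at least 6.32 elsewhere. No gene was higher in sgAAVS1 than in all 5. Of the genes higher in a knockdown, 63 in TASOR, 56 in TASOR2, 48 in MPP8 and 94 in PPHLN1 were also higher in untransduced cells. Of the genes near the targeted promoters, YAF2, whose start lies 98 bases from that of PPHLN1, differed by 0.12 ± 0.17 in the PPHLN1 knockdown.

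Gene differences from sgAAVS1 spread more widely in the TASOR2 mean than in the others: the robust SD over 9320 genes of mean log2 value 5 to 9 was 0.22, against 0.12 in untransduced cells, 0.10 in TASOR, 0.07 in MPP8 and 0.08 in PPHLN1. The counting SD in TASOR2 was 1.07 times the smallest of the others, which argues against counting error as the reason for the wider spread. The ratio of the TASOR2 to the PPHLN1 spread was 2.75 before and 2.02 after the GC trend was removed, above the bound of 1.5 set beforehand. Against TASOR, the widest other knockdown, the ratio went from 2.12 to 1.45, and against untransduced cells it was 1.67 after removal. GC content thus accounts for part of the spread; it does not account for all of the difference from PPHLN1, and for the difference from TASOR, where 1.45 lies between the bounds, this stays open. The bounds had been set for the ratio to PPHLN1. With the trend on transcript length removed the ratio to PPHLN1 was 2.77 and that to TASOR 2.08, which argues against length. Across the 9320 genes the TASOR2 difference had a Spearman correlation of -0.25 with the MPP8 and -0.11 (-0.1094) with the PPHLN1 difference, although a shared control adds to it, and of -0.06 and 0.19 with the GC trend removed. This argues against an effect shared with MPP8 and PPHLN1 loss as the whole cause. A smaller shared part stays open for called genes: over the 159 genes higher in TASOR2 against both controls, medians relative to untransduced cells were 1.64 in TASOR2, 0.30 in MPP8, 0.31 in PPHLN1 and 0.27 in TASOR, and over the 212 lower genes they were -0.08, -0.09 and -0.07 in MPP8, PPHLN1 and TASOR, where TASOR2 had quartiles of -1.80 and -1.26. These genes were chosen partly against the same untransduced mean, whose error can shift the medians of the other knockdowns in the same direction. Over all tested genes, the median differences from untransduced cells were 0.08 in MPP8, 0.13 in PPHLN1 and 0.12 in TASOR, and were not subtracted. A difference in a single TASOR2 library or guide, a library batch, and an effect of TASOR2 loss alone also stay open, since single libraries were not analysed here and the mean holds 2 of 3 listed libraries.

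Of the 71 interferon-stimulated genes 20, 17 and 23 were higher in the TASOR2, MPP8 and PPHLN1 means and 1 in TASOR, and the list medians were 0.44, 0.42, 0.42 and 0.04. With no filter on low values they were 0.42, 0.48, 0.53 and 0.29. The TASOR median moved with the median of all genes, which went from 0.16 to -0.09. Without the filter, 43.0% of genes in TASOR and in sgAAVS1 carried the lowest value, which marks no reads. That value was -2.95 in TASOR and -2.78 in sgAAVS1, and the median of all genes follows it. The 0.29 is therefore not a measure of the interferon contrast. A single scale factor per mean could not move these medians, which are relative to all genes. After quantile normalization the lowest of the 3 medians was 0.38 (0.3756), which argues against scaling that varies with the level of a gene. Among random lists matched on mean value and GC the lowest percentile was 100, which argues against GC content. A difference in RNA quality between libraries stays open, since lists that follow it were split between the same knockdowns. In TASOR2, MPP8 and PPHLN1 the medians were 0.13, 0.08 and 0.04 for mitochondrially encoded genes and 0.08, 0.04 and 0.06 for small structured RNAs, and in TASOR -0.05 and -0.21. Ribosomal protein genes were at 0.02, 0.02 and -0.01, and at -0.12 in TASOR. Guide-specific responses, culture batches and an effect of TASOR2, MPP8 or PPHLN1 loss that TASOR loss lacks also stay open and may contribute.

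Reads per transcript base in sgAAVS1 at the top 0.1% of genes were 2.18 times those at the top 1%, between the bounds of 2 and 4. This ratio does not decide whether duplicate reads were removed before counting. Among longer abundant transcripts, MALAT1, ACTB, FTH1 and MT-CO1 had 1.04, 1.01, 0.97 and 1.24 reads per base. AHNAK and HSPG2 had 0.39 and 0.53. These genes are examples, so a limit near 1 read per base, as removal of duplicates could give, was not tested on them. Short RNA genes stood far above these values: SNORA67 had 11.6 reads per base, MIR6820 7.08 and MIR6080 3.73, against 0.61 at the top 1%. The short RNA genes were chosen after their values were seen. All of the 20 genes with the highest values had transcripts over 5000 bases, and the highest took 0.123% of its column. If duplicates were removed, differences of transcripts with many reads per base, short or long, could be compressed. No biological explanation was tested.

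A hypothesis that TASOR and TASOR2 act on the same zinc finger genes was tested on the 61 numbered zinc finger genes higher in PPHLN1. The MPP8 difference from untransduced cells lay above both the TASOR and the TASOR2 one in 36 of them (59.02%), between the bounds of 50 and 60 set beforehand, and the median of MPP8 minus the sum of the 2 was -0.07. The result decides nothing. A second hypothesis, that genes without introns are over-represented among genes higher in TASOR, was not borne out among named genes. Of 56 named genes higher against both controls, 2 had a single exon (3.57%, beside a random median of 5.36%), at the 27.8th percentile of random lists (27.82). The 83 genes higher against both controls also include genes named only by a clone or locus identifier, which the test left out. Exon number was that of the transcript with the most exons.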
